A study of Mus musculus with 6 samples.

How the data were processed

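RNA was measured by high-throughput sequencing in mouse regulatory T cells (Treg cells), the Foxp3-expressing CD4 T cells that restrain immune responses. Per the labels, cells were sorted as live CD4 cells positive for the yellow fluorescent protein of a Foxp3-driven Cre allele, from male mice, and barcoded libraries were mixed and run on an Illumina NovaSeq. The 6 libraries form 2 groups of 3, KO and WT, named after the genotype in the sample titles. Crlf2 encodes the receptor subunit specific for the cytokine TSLP. Its floxed allele was combined with the Foxp3-driven Cre. Title and genotype tag place each sample in the same group, but the strain line of each description names the other strain. Groups were taken from title and genotype tag. This grouping, the main test, the gene lists, the rule for naming genes and the alternatives, unless stated otherwise, were fixed before the data were examined. The labels name spleen and lymph node as the tissue, whereas the title of the deposited table mentions lung.

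The authors deposited raw read counts per RefSeq transcript, with the transcript length, per the file headers and the values. Per the submitters' processing notes, bcl2fastq, Bowtie2 2.2.6, TopHat2 2.2.1 and the mouse build mm10 were used. The counting program, the annotation release, the handling of strand and of reads mapping to several places, and any filter are not given in the sources used here. The table holds 31682 transcript rows for 23992 gene symbols, and 4343 symbols have several rows. Isoforms of a gene repeat the reads they share, so the row with the highest total was kept for each symbol. Reads can also be counted for overlapping or near-identical genes: 30 tested symbols had counts identical to another symbol in all 6 libraries. Without a known strand setting, reads of a gene and of an overlapping antisense gene cannot be separated. All rows named a gene, no per-sample column was left unused (0), and no mitochondrially encoded gene was in the table.

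Depth differed between libraries. After keeping 1 row per symbol, the totals were 7971181, 1439736 and 12180569 counts for WT replicates 1 to 3, and 9649601, 11583969 and 18352401 for KO replicates 1 to 3. A count of 3, the limit that a count of 0 allows, equals 2.05 CPM (counts scaled to library size) in WT replicate 2 and 0.157 to 0.401 CPM in the other libraries. Such limits, and exact intervals on ratios of counts, cover counting error only.

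Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 12720. Factors from the trimmed mean of M values (TMM) were applied, and KO was compared with WT by edgeR 4.0.16's quasi-likelihood F-test (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. P-values were adjusted by Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. CPM values are TMM-normalized over the tested genes. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of F. No block was used, because the labels do not say what a replicate number stands for. Nor do they say that replicates came from separate animals, so p-values measure only the spread between these samples. On counts simulated from the means, library sizes and dispersions of the 12720 genes, with 200 genes changed, the test recovered 23.6% of 2-fold and 63.2% of 4-fold changes. In these 10 simulations 9.02% of the calls were unchanged genes, which is above the nominal level.

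The 38 fixed gene lists covered Treg identity and function, T helper subsets, cytokine signalling, homing, cell processes, markers of other cell types and sex-linked genes. Lists with at least 3 tested genes (34 lists) were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. In 20 simulations without change, camera called 12 of 672 list tests. Genes were simulated independently of one another, whereas the estimated inter-gene correlation of the interferon list was 0.756. This rate therefore does not hold for lists of correlated genes. Genes named in the text follow a rule. Crlf2 and Foxp3 are always named. So are the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose mean was at least 5 CPM in the higher group, leaving out unnamed loci and receptor segments. For each list of Treg, T cell, helper, signalling or homing genes, up to 4 called members of smallest p are named, or up to 2 where none was called. For other lists that passed the set test, and for sex-linked genes, the 3 members of highest CPM are named. If fewer than 5 genes had been called in a direction, the 5 of smallest p would have been named. Genes named outside this rule are marked as such. Some genes that the rule names are counted but not reported here.

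The fixed alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with and without sample quality weights, non-robust estimation, other filters and thresholds, all transcript rows, the replicate number as a block, an estimated inter-gene correlation, fry, and leaving out each library. Scaling to 13 pan-T cell genes, thinning every library to the depth of WT replicate 2, the log2 share of lung epithelial markers as a covariate and recounting list members under each alternative were added after the data had been seen. Positions are from GENCODE M21, whose build GRCm38 corresponds to mm10.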

Results

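Transcripts were counted in 6 libraries of mouse Treg cells, 3 labelled KO and 3 labelled WT, to compare Treg cells without and with Crlf2, the TSLP receptor subunit. Going by the title of the series, the question was whether TSLP acting on Treg cells helps to maintain Treg identity. Library totals ranged from 1439736 counts (WT replicate 2) to 18352401 counts (KO replicate 3), and 12720 genes were tested. The 3 KO libraries resembled one another more closely (Pearson r of log2 CPM across genes 0.954 to 0.963) than the 3 WT libraries did (0.874 to 0.894). Pairs of a KO and a WT library had r of 0.873 to 0.914, so by this measure the WT libraries were no closer to one another than to KO libraries. In no pair of libraries did the counts agree within sampling noise, the lowest chi-square per degree of freedom being 13.2.

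Crlf2 itself was far lower in the libraries labelled KO. The gene lies on chromosome 5 (mm10, 109554709 to 109558993, minus strand, protein coding). It had 93, 84 and 68 reads in KO replicates 1 to 3, and 694, 213 and 1111 reads in WT replicates 1 to 3. This corresponded to 6.44 ± 2.76 CPM in KO (SD, n = 3) and 115 ± 27.7 CPM in WT (SD, n = 3), a log2 fold change of -4.16 (SE 0.36, edgeR adjusted p = 0.0047). The direction goes with the titles and genotype tags, and against the strain line of the sample descriptions. The table counts whole transcripts, so reads from exons outside the floxed part, or from other cells, are included. Foxp3, the transcription factor that defines Treg cells (chromosome X, 7573644 to 7595245, plus strand), was at 434 ± 52.1 CPM in KO and 370 ± 148 CPM in WT (SD, n = 3 each). Its log2 fold change was 0.23 (SE 0.30, edgeR adjusted p = 0.763), a difference within the spread between replicates. The lowest Foxp3 value was that of WT replicate 3.

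In KO, 14 genes of the type I interferon response fell and 6 genes of effector Treg cells rose. In all, 221 genes were called by edgeR, 96 higher and 125 lower in KO, and 166 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 2018 genes. The KO and WT libraries did not overlap for any of the 221 genes. Of the 12720 tested genes, 2797 (22.0%) had groups that did not overlap, where chance alone gives 10% on average. Because genes vary together, the share in 1 set of libraries can lie far from that average by chance. Scaled to pan-T cell genes instead of TMM, the split was 25 higher and 157 lower, with the median of all genes at -0.34 instead of -0.04 on the log2 scale. The number of calls changed when single libraries were left out. It was 518 without WT replicate 3, but 4 without KO replicate 1, 124 without KO replicate 2, 7 without KO replicate 3, 33 without WT replicate 1 and 22 without WT replicate 2. Of the 46 called genes that are named by rule, 45, 3, 27, 5, 14 and 13 were called in the same direction in those fits, respectively. With the lung epithelial share as a covariate, chosen after the data were seen, edgeR called 0 genes, 1125 had an unadjusted p under 0.05, and the log2 fold change of Crlf2 was -3.96 (SE 0.42, edgeR adjusted p = 0.056).

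Of the 34 lists tested, the type I interferon response had the smallest camera p. All 22 tested members had lower values in KO, with a median log2 fold change of -2.33, and 14 were called lower. Rsad2, which encodes the antiviral protein viperin, fell from 88.4 ± 8.19 CPM in WT to 13.8 ± 5.63 CPM in KO (SD, n = 3 each; log2 fold change -2.68, SE 0.28, edgeR adjusted p = 0.0092). Isg15, a ubiquitin-like modifier, fell from 158 ± 41.5 to 26.8 ± 10.4 CPM (log2 fold change -2.56, SE 0.31, edgeR adjusted p = 0.013). Bst2 (tetherin) changed by -2.18 (SE 0.25) and Oas3, an antiviral sensor of double-stranded RNA, by -2.39 (SE 0.28) on the log2 scale. The 8 members that were not called had log2 fold changes of -0.82 to -2.98. All 22 were lower when adjusted over the list alone. The list passed camera downward (adjusted p = 1.45e-23). With an estimated correlation its adjusted p was 0.565, and fry gave an adjusted p = 0.0679. edgeR called no member without KO replicate 1, KO replicate 3 or WT replicate 2, where 20, 22 and 20 members had an unadjusted p under 0.05, and it called 2 without WT replicate 1. The list's median stayed between -2.07 and -2.84 in these and the other fits that left out 1 library. Without WT replicate 3, in which erythroid markers took 14.5% of the counts (7.84% with near-identical genes counted once), 15 were called. Lung epithelial markers also passed camera downward (adjusted p = 1.17e-06; adjusted p = 0.638 with an estimated correlation), with a median log2 fold change of -1.73 and shares of 1.72% to 7.62% of the counts in WT and 0.254% to 1.99% in KO. With their share as a covariate, the interferon median was -1.90 and no member was called by edgeR, 19 having an unadjusted p under 0.05.

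**Figure D1:**
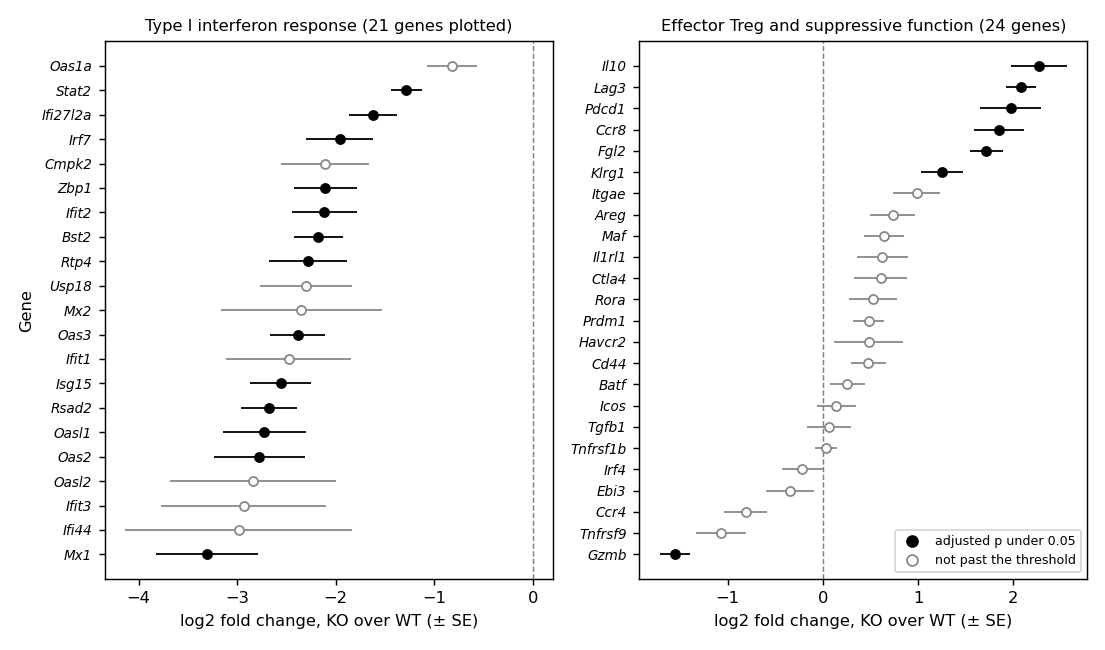
Log2 fold changes of KO over WT (x axis, ± SE, 3 libraries per group) for 21 of the 22 tested interferon genes and all 24 tested effector Treg genes (y axis). Filled points are called genes: 13 of the 21 interferon genes plotted lie below 0 and are called, and among 24 effector genes 6 lie above 0 and 1, Gzmb, below.

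Treg effector genes moved in both directions, with more rises than falls. Of 24 tested genes of effector Treg cells and suppressive function, 6 were called higher in KO and 1 lower. Il10, which encodes a suppressive cytokine, rose from 43.1 ± 18.4 CPM in WT to 200.1 ± 17.4 CPM in KO (SD, n = 3 each; log2 fold change 2.27, SE 0.29, edgeR adjusted p = 0.016). Lag3, an inhibitory receptor, rose from 72.4 ± 11.4 to 304 ± 36.5 CPM (log2 fold change 2.08, SE 0.16, edgeR adjusted p = 0.0047). Fgl2, a secreted immunosuppressive protein, rose by 1.72 (SE 0.17), the chemokine receptor gene Ccr8 by 1.85 (SE 0.26) and Pdcd1, which encodes PD-1, by 1.97 (SE 0.32) on the log2 scale. Klrg1, the sixth riser and outside the naming rule, had a log2 fold change of 1.25 (SE 0.22). Gzmb, which encodes the cytotoxic protease granzyme B, fell from 204 ± 15.9 to 69.2 ± 12.1 CPM (log2 fold change -1.56, SE 0.16, edgeR adjusted p = 0.0077). Adjusted over the list alone, 10 were higher and 3 lower. The list passed camera upward (adjusted p = 1.17e-06), with an adjusted p = 0.638 with an estimated correlation. Members called higher numbered 7 without WT replicate 3, but 1 without KO replicate 1, 1 without KO replicate 3, 2 without WT replicate 1 and 3 without WT replicate 2. A set of 13 pan-T cell genes, chosen after the data were seen and with no called member, had a median log2 fold change of 0.22, and of 0.07 without WT replicate 3. The effector list's median of 0.51 became 0.26 when scaled to these genes, with 6 members called higher and 3 lower. Macrophage and monocyte markers took 0.173% to 0.198% of the counts in KO, and 0.0662%, 0.0943% and 0.547% in WT replicates 1 to 3.

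The core Treg signature did not pass camera with all 6 libraries. Of 24 tested members only Tigit, an inhibitory receptor gene, was called, with a log2 fold change of 1.09 (SE 0.21, edgeR adjusted p = 0.0483). Among the fits that left out 1 library, Tigit was called in the one without WT replicate 3 and in no other. It was also not called with DESeq2's size factors, without robust estimation or when scaled to pan-T genes. The list's median was -0.11 while camera pointed upward (adjusted p = 0.509), so the signs differed. Of the 24 members, 2 were higher and 2 lower when adjusted over the list alone. The direction depended on WT libraries: the list passed camera downward without WT replicate 3 (adjusted p = 0.0130), which had the lowest Foxp3 level, and upward without WT replicate 1. Over all alternatives its adjusted p ran from 0.0130 to 0.860. Without WT replicate 3, 2 members were called higher and 4 lower.

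**Figure D2:**
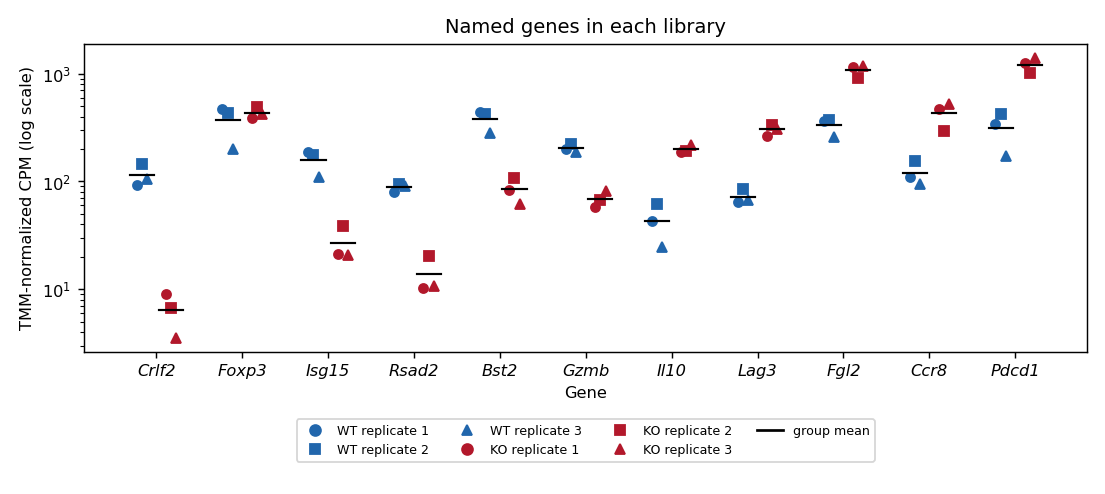
TMM-normalized CPM (y axis, log scale) of 11 genes (x axis) in each of the 3 WT and 3 KO libraries, with group means as bars. Crlf2 and the interferon genes Isg15, Rsad2 and Bst2 lie lower in all KO libraries, Il10, Lag3, Fgl2, Ccr8 and Pdcd1 lie higher, and Foxp3 overlaps.

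Genes responsive to IL-2 and STAT5 leaned lower in KO. Of 20 tested, 19 had a negative log2 fold change (median -0.52), and Gzmb, Socs1 and Socs3 were called lower. Socs1, a feedback inhibitor of cytokine signalling that interferons also induce, fell from 373 ± 88.9 to 171 ± 4.17 CPM (log2 fold change -1.12, SE 0.18, edgeR adjusted p = 0.027). Socs3, of the same family, changed by -0.68 (SE 0.13, edgeR adjusted p = 0.0497). Its call was lost with DESeq2's size factors or upper-quartile factors in edgeR, without robust estimation, without the low-count filter and when scaled to pan-T genes. When adjusted over the list alone, 7 were lower. This list passed camera (adjusted p = 2.01e-06) and fry (adjusted p = 0.00133), with an adjusted p = 0.170 with an estimated correlation. Without WT replicate 3, 6 members were called. Without KO replicate 1 edgeR called none, and 1 was called in each of the other fits that left out 1 library. Among 9 genes of the TSLP and IL-7 receptors and their kinases, 2 were called lower, Crlf2 among them, and Il7r was called higher. Il7r, whose product pairs with that of Crlf2 in the TSLP receptor, rose from 121 ± 25.3 to 294 ± 29.8 CPM (log2 fold change 1.29, SE 0.17, edgeR adjusted p = 0.016). This list did not pass camera (adjusted p = 0.344), and adjusted over the list alone the counts were again 1 higher and 2 lower.

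Genes of resting or central T cells leaned lower: 16 of 17 tested members had a negative log2 fold change (median -0.73), 2 of them called lower, while Il7r rose. Ly6c1 fell from 73.8 ± 9.93 to 13.4 ± 2.54 CPM (log2 fold change -2.46, SE 0.21, edgeR adjusted p = 0.0047). Of the 17 genes, 10 were lower and 1 higher when adjusted over the list alone. The list passed camera downward (adjusted p = 9.84e-06), with an adjusted p = 0.638 with an estimated correlation. The median was -0.46 without WT replicate 3, with 4 members called lower, and -1.12 when scaled to pan-T genes, with 1 called lower. Without KO replicate 1 edgeR called none (11 at an unadjusted p under 0.05), and 1 was called lower in each of the other 4 fits that left out 1 library. Among 11 genes higher in conventional than in regulatory CD4 T cells only Il7r was called, also when adjusted over the list alone, and camera did not pass (adjusted p = 0.198). Values of Ly6c2 and Igfbp4, chosen after they were seen and not called, were 75.8 ± 79.0 and 97.0 ± 90.4 CPM in WT against 6.36 ± 1.92 and 22.7 ± 4.57 CPM in KO.

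Of the T helper lists, Th2 passed camera upward (adjusted p = 0.00233), with an adjusted p = 0.485 with an estimated correlation. Of its 15 tested genes 2 were called, both higher: Ccr8, and Pparg, a nuclear receptor found in tissue Treg cells and in alveolar macrophages (10.7 ± 3.69 CPM in WT, 42.2 ± 9.03 CPM in KO, log2 fold change 1.93, SE 0.30, edgeR adjusted p = 0.026). Scaled to pan-T genes, 1 Th2 gene (Ccr8) was called higher and 2 lower, so which genes were called depended on the scaling. Those 2, Ccr4 and Il4ra, chosen after their values were seen, already had negative log2 fold changes with TMM (-0.81 and -0.54). They were also called lower without WT replicate 3, where 3 Th2 genes were called higher. edgeR called no Th2 gene without KO replicate 1, KO replicate 3, WT replicate 1 or WT replicate 2, where 8, 6, 10 and 10 had an unadjusted p under 0.05. Chil3, an alveolar macrophage transcript, was at 1478 to 1699 CPM in KO and at 131, 388 and 3779 CPM in WT replicates 1 to 3. The Th2 cytokine gene Il4, outside the naming rule, was at 12.2 ± 18.0 CPM in WT and 3.91 ± 1.04 CPM in KO, and was not called. Gata3, also outside the rule and not called, was at 776 ± 248 CPM in WT and 1558 ± 224 CPM in KO (log2 fold change 1.01, SE 0.24, edgeR adjusted p = 0.0904). Of the 15 Th2 genes, 10 had a positive and 5 a negative log2 fold change (median 0.62). When adjusted over the list alone, 6 Th2 genes were higher and 2 lower. The Th1, Th17 and Tfh lists did not pass camera (adjusted p = 0.211, 0.381 and 0.509). Of 16 Th1 genes the chemokine receptor gene Cxcr6 was called, rising by 1.67 (SE 0.24). None of 11 Th17 genes was called by edgeR, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05 in edgeR. Those of smallest p were Ahr with a log2 fold change of -0.52 (SE 0.15) and Il17a with -2.38 (SE 0.89) at 2.61 ± 1.10 CPM in WT. Of 11 Tfh genes, Tox2 (1.61, SE 0.25) and Pdcd1 rose, and Bcl6, the transcription factor of follicular T cells, fell from 40.5 ± 4.38 to 19.2 ± 1.04 CPM. edgeR called no Tfh gene without KO replicate 1, KO replicate 3, WT replicate 1 or WT replicate 2 (5, 8, 8 and 7 at an unadjusted p under 0.05), and Cxcr6 was not called without the first 3 of these. Bcl6 was also not called when scaled to pan-T genes. The counts adjusted over the list alone were 1 higher and 2 lower for Th1, 0 for Th17, and 2 higher and 5 lower for Tfh.

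Homing receptors did not pass camera as a list (adjusted p = 0.345). Of 26 tested, Ccr8, Cxcr6 and Itgb8 were called higher, and 2 genes, Gpr183 among them, lower. Itgb8, which encodes part of an integrin that activates TGF-beta, was at 19.1 ± 0.766 CPM in KO and at 2.94, 5.47 and 3.59 CPM in WT replicates 1 to 3 (log2 fold change 2.33, SE 0.35, edgeR adjusted p = 0.023). Gpr183, an oxysterol receptor gene, was at 67.2 ± 2.39 CPM in KO and 138 ± 12.4 CPM in WT (edgeR adjusted p = 0.014). No homing gene was called by edgeR without KO replicate 1, KO replicate 3 or WT replicate 1 (12, 11 and 12 at an unadjusted p under 0.05), and 1 higher and 1 lower without WT replicate 2. Of 15 NF-kB pathway genes, Nfkb1 (log2 fold change 1.12, SE 0.19) and Tnfaip3 (0.57, SE 0.11) were called higher, and Bcl3 lower (-0.83, SE 0.15). Scaled to pan-T genes, Bcl3 was called and the other two were not. No NF-kB gene was called when any 1 of those 3 libraries or WT replicate 2 was left out, where 6 to 8 had an unadjusted p under 0.05, and only Nfkb1 without KO replicate 2. The NF-kB and immediate early lists gave camera adjusted p = 0.345 each, and of 25 immediate early and heat shock genes only Tnfaip3 was called. The immediate early list passed camera upward without WT replicate 3 (adjusted p = 0.000202, range over the alternatives 0.000202 to 0.918). When adjusted over the list alone, 4 homing genes were higher and 8 lower, 2 NF-kB genes were higher and 5 lower, and 1 immediate early gene was higher.

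The largest single-gene rises included genes little studied in T cells. Esm1, which encodes the secreted proteoglycan endocan, rose from 2.19 ± 1.09 to 27.9 ± 5.08 CPM (log2 fold change 3.87, SE 0.40, edgeR adjusted p = 0.0077). Col18a1, a basement membrane collagen gene, rose from 7.34 ± 3.86 to 74.4 ± 14.8 CPM (log2 fold change 3.52, SE 0.35). Calca, which encodes calcitonin and the neuropeptide CGRP, rose by 2.96 (SE 0.39), and Vipr2, a receptor gene for vasoactive intestinal peptide, by 2.81 (SE 0.53). Gfra4, Scg5, Zan, Cib2 and Wisp1 had log2 fold changes of 3.85, 3.49, 3.12, 2.84 and 2.81. Ky had 49, 95 and 83 reads in KO and 2 reads over the 3 WT libraries, a ratio of 52.8 (exact 95% interval 14.5 to 439). Among the largest falls besides Crlf2 were Cxcl10, an interferon-induced chemokine gene (86.4 ± 38.0 to 8.37 ± 2.04 CPM, log2 fold change -3.35, SE 0.36, edgeR adjusted p = 0.0092), the antiviral gene Mx1 (-3.31, SE 0.51) and the interferon-inducible GTPase gene Iigp1 (-3.18, SE 0.37). Lrrc25, Tmcc3, Tnp2, Rhpn2 and Calml3 had log2 fold changes of -3.15, -3.30, -3.44, -5.48 and -5.63, the last 2 at 7.48 ± 2.69 and 5.10 ± 3.96 CPM in WT. Of the 46 called genes named by rule, Calml3 was the 1 not called without WT replicate 3. Upp1 had 2 reads over the KO libraries and 84 over the WT libraries, a KO to WT ratio of 0.0111 (exact 95% interval 0.00132 to 0.0413).

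Cell cycle genes leaned lower in KO, with 1 member called. Of 40 tested, 35 had a negative log2 fold change (median -0.58). The called member was Birc5, a mitotic gene named here after its value was seen (-1.17, SE 0.23, edgeR adjusted p = 0.047). The 3 most abundant members, Mcm6, Stmn1 and Mcm3, had log2 fold changes of 0.17, -0.23 and -0.26 and were not called. Of the 40, 9 were lower when adjusted over the list alone. The list passed camera downward (adjusted p = 1.26e-06), with an adjusted p = 0.638 with an estimated correlation, and fry gave an adjusted p = 0.0945. In the fit without WT replicate 3, 4 members were called lower, and edgeR called none in the other fits that left out 1 library, where 12 to 16 had an unadjusted p under 0.05. Birc5 was also not called without robust estimation. With all 6 libraries, edgeR called no member among 15 glycolysis, 35 oxidative phosphorylation, 19 cholesterol synthesis, 29 ribosomal protein and 18 apoptosis genes. At an unadjusted p under 0.05 there were 4, 2, 4, 1 and 8 genes, and DESeq2 called 0, 0, 1, 0 and 5 while limma-voom called 0 in each. None of these lists passed camera (adjusted p = 0.557, 0.129, 0.556, 0.127 and 0.293). The oxidative phosphorylation and ribosomal lists passed downward without KO replicate 3, and the apoptosis list upward without WT replicate 3. When adjusted over the list alone, 4 apoptosis genes were higher and 1 lower, and 0 genes of the other 4 lists changed.

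Transcripts of other cell types were present in every library, at different levels. The 14 lung epithelial markers made up 7.62%, 1.72% and 2.26% of the counts in WT replicates 1 to 3, and 1.61%, 1.99% and 0.254% in KO replicates 1 to 3. Scgb1a1, the secretory protein of airway club cells, was at 76749 CPM in WT replicate 1 and at 2167 CPM in KO replicate 3. This gene alone took 7.20%, 1.62% and 1.99% of the counts in WT replicates 1 to 3. In KO replicates 1 to 3 it took 1.52%, 1.88% and 0.226%. The lung epithelial share, also where used as a covariate, therefore mostly follows this 1 airway gene. The lung epithelial list passed camera as lower in KO (adjusted p = 1.17e-06; adjusted p = 0.638 with an estimated correlation), with no member called by edgeR, 5 at an unadjusted p under 0.05 and 2 called by DESeq2. Log2 fold changes were -1.77 (SE 1.00) for Scgb1a1, -2.15 (SE 0.96) for the surfactant gene Sftpa1 and -2.49 (SE 1.06) for Scgb3a2. WT replicate 3 stood apart in blood cell transcripts. Erythroid genes took 14.5% of its counts, against 0.172% to 0.688% in the other 5 libraries. These shares count some reads repeatedly, because haemoglobin genes such as Hbb-bs and Hbb-b1 had nearly the same counts and their reads cannot be assigned to either. With genes of nearly the same counts taken once, the share was 7.84% in WT replicate 3 and 0.0866% to 0.347% elsewhere. The B cell gene Cd79a was at 153 CPM in WT replicate 3 and at 2.73 to 10.9 CPM elsewhere, and the NK cell gene Gzma at 303 against 4.49 to 17.1 CPM. The B cell, dendritic cell and erythroid lists passed camera as lower in KO (adjusted p = 0.00469, 0.000671 and 0.0165; 0.691 each as adjusted p with an estimated correlation). Without WT replicate 3 they did not (adjusted p = 0.725, 0.611 and 0.400). Over the alternatives their adjusted p ran down to 1.53e-06 for B cells and 1.34e-06 for dendritic and erythroid cells. The macrophage and monocyte list, by contrast, passed upward without WT replicate 3 (adjusted p = 2.21e-05) and downward without WT replicate 1 (adjusted p = 0.000145; range over the alternatives 2.21e-05 to 0.836), so its direction depended on the WT libraries. In the fit without WT replicate 3 its median was 1.40, against -0.80 with all 6 libraries. Lyz1, Lyz2, Csf1r, Cd14 and Cd68, named after their values were seen, were then called higher in KO and Ly6c2 lower. Of the dendritic cell genes only Bst2, which is also on the interferon list, was called with all 6 libraries. When adjusted over the list alone, 2 dendritic cell genes were lower, and of the B cell, erythroid and lung epithelial genes 0. Cd79b had a log2 fold change of -1.45 (SE 1.00), and Cd74, H2-Ab1 and Cst3 of -1.83 (SE 0.87), -1.71 (SE 0.99) and -0.29 (SE 0.51). No member of the plasma cell, NK cell, gamma-delta T cell, macrophage, alveolar macrophage, neutrophil, eosinophil, platelet or endothelial lists was called by edgeR with all 6 libraries, and these lists did not pass camera (adjusted p from 0.0882 to 0.509). Each held 0 to 3 genes at an unadjusted p under 0.05, and DESeq2 called 0 or 1. When adjusted over the list alone, 1 plasma cell and 1 NK cell gene were lower and 1 platelet gene was higher. For the 3 platelet genes the median was 0.72 and the mean -0.21, with camera upward. Without WT replicate 1, in contrast, 22 lists passed camera. Besides lists of other cell types, those gained were the core Treg, conventional T cell and Th1 lists. The CD8 T cell, mast cell and fibroblast lists had fewer than 3 tested genes. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were at 21.8 ± 3.95, 21.7 ± 6.97 and 17.1 ± 1.80 CPM in KO and at 35.1 ± 8.16, 28.2 ± 2.18 and 17.6 ± 3.75 CPM in WT. The sex-linked list was not called (camera adjusted p = 0.293).

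**Figure D3:**
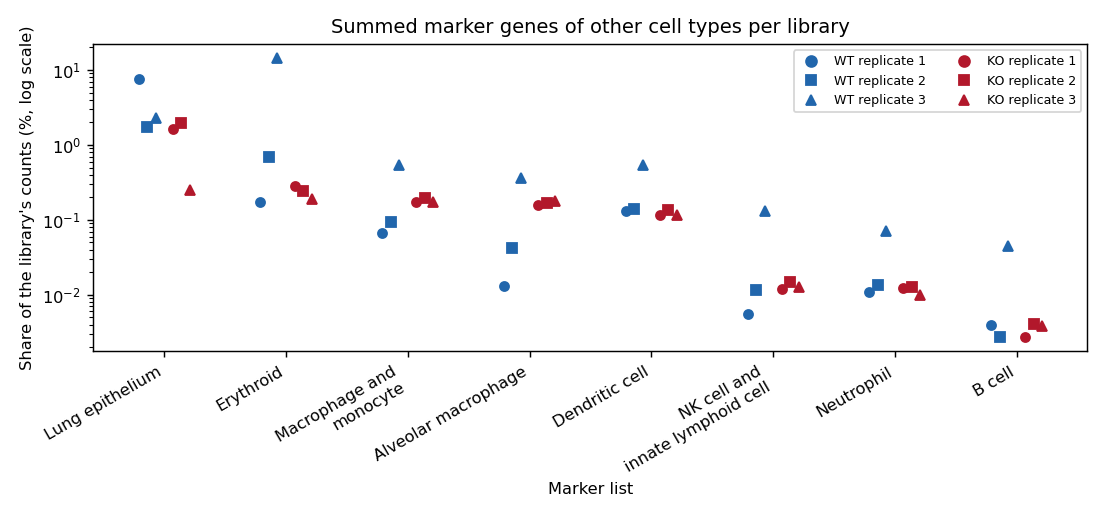
Summed counts of marker genes of 8 other cell types (x axis) as a share of each library's counts (y axis, percent, log scale), 1 point per library. WT replicate 3 is highest for all lists but lung epithelium, with 14.5% erythroid counts (haemoglobin genes that share reads are each counted), and WT replicate 1 has the highest lung epithelial share, 7.62%.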

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

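Scaling to pan-T genes, thinning to 1 depth, the lung epithelial share as a covariate and the recounts of list members were chosen after seeing the data. In the alternatives run, no named gene that was called reversed its direction. Crlf2 was called in every fit (log2 fold change -3.84 to -4.47) but the one with the lung covariate (-3.96, edgeR adjusted p = 0.056). That fit, with 3 instead of 4 residual degrees of freedom, called 0 genes (0 higher, 0 lower), 0 of the named calls, 0 interferon genes and 0 effector genes by edgeR, with 1125 genes, 19 interferon and 11 effector genes at an unadjusted p under 0.05. The count of 221 genes became 937 with DESeq2 (384 higher, 553 lower), which started from 17187 instead of 12720 genes and called all 221. It became 344 with all transcript rows (204 lower), where isoforms of a gene count repeatedly, and 505 at an adjusted p under 0.1. Genes higher in KO numbered 63 without robust estimation and 25 when scaled to pan-T genes, and genes lower in KO 221 with sample quality weights and 191 after thinning. The cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 4 to 518 genes (2 to 242 higher, 2 to 276 lower), 3 to 45 of the 46 named calls, 0 to 19 interferon genes and 1 to 7 effector genes. Of 10 lists passing camera, 0 passed with an estimated correlation and 1 with fry, and leaving out 1 library gave 10 to 22 lists. Depth limits WT replicate 2 most: a count of 0 there allows up to 2.05 CPM.

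With the replicate number as a block, 123 genes were called (32 higher), 102 of them shared with the fit without it. Of the named calls 26 were kept, and 3 effector genes were called. All 10 lists passed again in their direction, among 15 that passed. Same-numbered samples correlated at 0.084, -0.147 and -0.044 in their deviations from the group means, and not every sample correlated best with its own number. With 3 libraries per group and other cell types differing between them, these values cannot exclude a shared litter, day or batch.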

Other observations

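The tests of the strain segment, of batch and of lung epithelial RNA for the interferon genes, both tests of lung transcripts, and the genes and gene families of the next paragraphs were chosen after the results were seen. The families were counted by name and not tested for enrichment. Of 18 tested interferon-inducible GTPases, which defend cells against intracellular pathogens, 9 were called lower and 0 higher (median log2 fold change -1.48), and 15 were called lower without WT replicate 3. Among them Gbp2 was at 41.6 ± 1.22 CPM in KO and 255 ± 77.9 CPM in WT (SD, n = 3 each; log2 fold change -2.61, SE 0.24, edgeR adjusted p = 0.00508). Slfn1, Slfn5 and Slfn8 were called lower among 8 Schlafen genes, and Ms4a4b, Ms4a4c and Ms4a6b among 7 Ms4a genes. Of 29 genes of MHC class I and antigen processing, Psmb9, Psmb10 and Tap1 were called lower and H2-Q2 higher, and 14 were called lower and 1 higher without WT replicate 3. Scaled to pan-T genes, 7 were lower and 0 higher. Of 12 Parp genes Parp9 was called lower, and 3 were without WT replicate 3. Of 11 Oas and Ifit genes, 8 of which are on the fixed interferon list, 4 were called lower. The medians of these 6 families were below 0 under every scaling tried, and in every fit that left out 1 library. Their calls were largely lost when other libraries were left out: edgeR called no member of any of them without KO replicate 1 or KO replicate 3, where 15 GTPases and 16 MHC class I genes had an unadjusted p under 0.05 in each. Of the GTPases 11 were called lower without KO replicate 2, 2 without WT replicate 1 and 1 without WT replicate 2, and of the MHC class I genes 0 in each.

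Among other called genes, Apobec3, a restriction factor gene, was at 39.3 ± 9.26 CPM in KO and 223 ± 42.1 CPM in WT (SD, n = 3 each; edgeR adjusted p = 0.0047). Adam8, which encodes a membrane protease, was at 316 ± 27.2 CPM in KO and 121 ± 9.51 CPM in WT. Ltb4r1, a leukotriene B4 receptor gene, was at 418 ± 132 and 111 ± 5.78 CPM, and Id2, a transcriptional regulator gene, at 708 ± 86.2 and 333 ± 52.4 CPM. Gpnmb, a gene also expressed by macrophages, had a log2 fold change of 2.74 (SE 0.34). Actb, which encodes beta-actin and often serves as a reference gene, was at 18344 ± 970 CPM in KO and 31852 ± 2402 CPM in WT (log2 fold change -0.80, SE 0.09, edgeR adjusted p = 0.00976). It was called lower under every scaling tried, but not without KO replicate 1, KO replicate 3, WT replicate 1 or WT replicate 2.

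The first pattern is the fall of interferon genes in KO. The tables argue against other cells in WT replicate 3 as its cause, since the list's median was -2.53 without that library. A strain segment carried with the floxed Crlf2 allele could not directly change the 17 list members on other chromosomes, whose median was -2.28. An effect of such a segment on distant genes was not tested and stays open. Within 10 Mb of Crlf2, 2 of 151 genes (Gbp8 and Oasl1) were called, against 212 of 11843 elsewhere (Fisher's exact test, two-sided p = 1). With so few calls near Crlf2 this test has little power and cannot exclude a segment. With the lung epithelial share as a covariate the median was -1.90 instead of -2.33, which argues against lung RNA as the whole cause. The lung list's own median was -0.63 instead of -1.73. Its shrinkage is built in, because the covariate is made of these genes, mostly of Scgb1a1. The remainder had a median SE of 0.49, with 2 of the 14 genes at an unadjusted p under 0.05 in edgeR. It cannot show whether lung RNA was fully accounted for. All 14 interferon calls ended, with a median SE of 0.41 instead of 0.37 and 3 instead of 4 residual degrees of freedom. A sort or library batch that follows the genotype cannot be told apart from the loss of Crlf2, because 0 labels name a batch, date or litter, and lower interferon signalling in Treg cells lacking Crlf2 stays open beside it as a candidate explanation.

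The second pattern is the rise of 6 effector Treg genes in KO. Without WT replicate 3 the smallest of their log2 fold changes was 1.07, which argues against its other cells as the whole cause. A larger share of T cell RNA in the KO libraries would raise pan-T genes as much. The smallest rise among the 6 exceeded the largest among 13 pan-T genes by 0.70 (the largest was 0.41 without WT replicate 3). The 6 were chosen for their rise, so this gap is partly built in and does not speak for the whole list. The list's median was 0.51 against 0.22 for the pan-T genes. Scaled to pan-T genes it was 0.26, with 6 members called higher. RNA of macrophages, which the sort on CD4 and the Foxp3 reporter would remove, stays open. Without WT replicate 3, 5 of the 13 macrophage markers were called higher in KO (the list passed camera downward without WT replicate 1). WT replicates 1 and 2 had lower macrophage shares (0.0662% and 0.0943%) than the KO libraries (0.173% to 0.198%), as this explanation requires. WT replicate 3 had the highest share (0.547%), yet each of the 6 genes was lower there than in every KO library. Its Il10 (24.8 CPM), Pdcd1 (174 CPM), Fgl2 (257 CPM) and Ccr8 (94.967 CPM) levels were the lowest of all libraries. Its Lag3 level (67.1 CPM) was above that of WT replicate 1 (64.7 CPM) and below the 265 to 337 CPM in KO. This comparison rests on 1 library. Also open are different proportions of Treg subsets, an effect of Crlf2 loss within cells and an unlabelled batch.

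The third pattern is the lung epithelial signal in libraries labelled spleen and lymph node, after a sort on CD4 and the Foxp3 reporter that would remove epithelial cells. All 14 airway and alveolar markers reached 1 CPM in all 6 libraries, a count that describes the pattern and does not decide its source. Spill of reads from 1 library into the others would give 1 ratio of the alveolar gene Sftpc to the airway gene Scgb1a1. This ratio spanned 13.6-fold, from 0.149% (95% exact interval 0.133 to 0.166) in KO replicate 2 to 2.02% (1.96 to 2.08) in WT replicate 3, which argues against spill from a single library. Lung material in the sorted preparations and spill from several libraries stay open. So does a sort of the cells from lung, which the title of the deposited table mentions and the tissue label does not. Since the labels give all samples 1 tissue entry, no biological explanation was tested.

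Other groupings of the samples were counted. The real split gave 221 genes (2018 at an unadjusted p under 0.05), and edgeR gave 0 in each of the other 9 splits (at most 654 unadjusted). For interferon genes called in 1 direction the real split gave 14 and the highest other 0 (at most 2 unadjusted). Thus 1 of the 10 splits reached the real count in both cases. For lists passing camera, 7 of the 10 splits gave at least the real 10, and the highest other gave 20. With 10 splits no share can fall under 0.05.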
